A study of Rattus norvegicus with 16 samples.

How the data were processed

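Expression in rat skeletal muscle was measured on single-colour short oligonucleotide arrays, each read out as 8799 probe sets, of which 59 are array controls. The 16 arrays form 3 groups: EOM (extraocular muscle, 4 arrays), TA_6h (skeletal muscle labelled TA with a collection time of 6 hours, 8 arrays) and TA_1h (the same muscle with a collection time of 1 hour, 4 arrays). The labels do not say from which event the hours count, and they give no collection time for EOM. They number the EOM arrays from 1 to 4. The TA arrays carry a number with the letter a or b, except 2 TA_6h arrays, numbered 1 and 2 without a letter. These were joined with arrays 1b and 2b, which is an inference, so that TA_6h was taken to hold 4 numbered samples and TA_1h 2, each on a pair of arrays. Arrays of the same number and group were averaged on the log2 scale and counted as 1 sample. Nothing in the labels says that the numbers mark separate animals, so p-values measure the spread between these samples, which may be technical.

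The deposited values are intensities on a linear scale, 1 per probe set and array. How the authors summarised the probes of a probe set is not given in the sources used here, and what follows about it was read from the values. The mean of each array's values without the highest and lowest 2% lay between 801.1 and 801.8 on every array, so the deposited intensities had been scaled to a common mean and were used as deposited. In the EOM columns 8549 of the 35196 intensities, or 24.3%, lie below 0, down to -9382. No TA intensity is at or below 0, and the lowest is 0.0219. These ranges differ between the EOM and TA columns in a way that points to another summary step for EOM, so muscle and summary step cannot be told apart in any comparison of EOM with TA. The number of arrays limits the precision of all comparisons.

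A floor was set at the 25th percentile of all intensities, 56.5, values under it were raised to it, and log2 was taken. The 7640 probe sets above the floor on at least 4 arrays, controls left out, were tested. A group whose arrays all lie at the floor has only a bound there, and its fold is given as "at least". Where part of the arrays of the lower group lie at the floor, the difference is a lower limit of its size on the log2 scale of averaged values, and the ratio of mean intensities can be smaller. Gene names come from a probe table of GEO's platform annotation: 7018 probe sets have 1 symbol, 308 have several and were not named, and 1473 are unlisted. Of the 7018, 6994 matched a current gene entry by gene number, and no symbol changed. For gene lists and named genes each gene was represented by the probe set with the highest mean, which gave 4317 genes.

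Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 3 groups in a single fit, with 7 residual and 2.83 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with calls at an adjusted p under 0.05. Every adjusted p for a probe set or gene below comes from this limma fit. Errors of log2 differences are limma standard errors, and errors of intensities are SDs over numbered samples. Folds are on the floored log2 scale. The 26 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over the lists. RNA quality was compared through control probe sets for Gapdh and beta-actin with two-sided exact permutation tests over numbered samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

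Named genes followed a rule set before the data were examined: the 12 genes with the largest positive and the 12 with the largest negative log2 difference from TA_6h among those called against both TA groups in the same direction, up to 4 called members per list with the largest differences, and all myosin heavy chain genes. For the TA groups the rule took called genes and named none. Genes named outside the rule are said to be so. The rule gives lower genes at the floor, so the 12 genes with the largest negative differences called against both TA groups among probe sets above the floor on all 16 arrays were added after the data were seen.

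On simulated data with normal noise of the SD of each real probe set, in 10 runs with 200 of 7640 probe sets changed, the fit recovered 10% of 1.5-fold, 39.6% of 2-fold, 84.2% of 4-fold and 94.6% of 8-fold changes between EOM and TA_6h, with 4.81% false calls. For EOM against TA_1h it recovered 26% of 2-fold and 69% of 4-fold changes, and for TA_6h against TA_1h 25.8% and 66.4%. No floor was applied to the simulated changes, and 200 changed probe sets are far fewer than the 3606 called between EOM and TA_6h. The rates therefore hold for the simulated setting and not for the real EOM comparisons. In 20 simulations with lists of 30 genes for EOM against TA_6h, camera called 100% of lists shifted by 0.8 on the log2 scale and 0% of unshifted lists. The simulated genes varied independently of each other, and none outside the shifted list differed between groups. In the real data the differences over all tested probe sets had an SD of 1.245, and camera sets a list against the other genes. The 100% therefore does not carry over to the real lists. In the real data the estimated correlation was 0.128 in the matrix, 0.137 in the ribosomal and 0.253 in the fast-fibre list. It was 0.0015 in the nerve and 0.00046 in the antioxidant list. The 0% therefore does not carry over to lists whose genes vary together.

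Alternatives fixed before the data were examined covered quantile normalization, scaling to the same median, floors at the 10th and 40th percentile, log2(value + 50) without a floor, the filter, the treatment of paired arrays, the label number as a block, fits of only 2 groups, an intensity trend with robust settings, a 2-fold minimum, the probe set per gene and leaving out each numbered sample. Camera on the fit with random blocks and on the trend fit used its pre-ranked form. Added after the data were seen were probe sets above the floor on all 16 arrays, fits without or with only 5 TA arrays that stand apart, a batch term for these arrays, a 4-fold minimum and the beta-actin middle over 3′ ratio.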

Results

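The series profiles gene expression in rat extraocular muscle, the small muscles that move the eye, beside another rat skeletal muscle labelled TA. The data comprise 4 EOM arrays (4 numbered samples), 8 TA_6h arrays (4 numbered samples) and 4 TA_1h arrays (2 numbered samples). Above the floor lay 66.3 to 67.3% of the probe sets on an EOM array and 74.7 to 81.1% on a TA array. Correlations of log2 intensities across tested probe sets ran from 0.943 to 0.971 between EOM arrays and from 0.732 to 0.817 between EOM and TA arrays. The TA arrays did not form a uniform set. On 5 of them (TA_1h 2b and TA_6h 3a, 3b, 4a and 4b) the beta-actin control gave a middle over 3′ ratio of 0.146 to 0.390, against 0.815 to 1.28 on the other 7 TA arrays and 0.891 to 0.978 in EOM. The other 7 TA arrays were not uniform either. Among them the middle Gapdh control gave 1299 on TA_1h 1a, 1433 on TA_1h 2a, 2184 on TA_6h 1b and 856 on TA_6h 2b. It gave 6698 to 51038 on all remaining arrays. Fits without the 5 arrays therefore keep arrays that differ in this control. They hold TA_6h replicates 1 and 2 and TA_1h replicates 1 and 2, the last on a single array. A call lost there can reflect fewer samples.

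The first comparison asks how extraocular muscle differs from TA muscle collected at 6 hours. Among probe sets with a gene symbol, the largest differences higher in EOM were in myosin heavy chains, the motor proteins of the thick filament. Myh8, the neonatal isoform, had an intensity of 7859 ± 943 (SD, n = 4) in EOM and 71.7 ± 30.2 (SD, n = 4) in TA_6h, a 104-fold difference (log2 6.70 ± 0.20, limma adjusted p = 4.3e-08). Myh13, the isoform named for extraocular muscle, was at 7677 ± 346 in EOM and 240 ± 98.2 in TA_6h, 36.2-fold higher on the floored log2 scale (log2 5.18 ± 0.32), with 7 of the 8 TA_6h arrays above the floor. The embryonic isoform Myh3 was 2.67-fold higher through its brightest probe set (log2 1.41 ± 0.44, limma adjusted p = 0.024), and 4 of its 5 probe sets were called higher, the other 3 of these by 17.4-, 10.96- and 5.49-fold. Among adult fast isoforms Myh2 (log2 -0.65 ± 0.20) and Myh4 (-0.65 ± 0.23) were called lower. Myh1 was not called (0.38 ± 0.21, limma adjusted p = 0.16). The slow isoform Myh7 was lower in both probe sets (brightest -0.81 ± 0.23, the other -2.04 ± 0.28). The 3 probe sets of Myh6 disagreed, with differences of -0.9997 and 1.98, both called, and 0.42, not called. The call for Myh4 was lost after quantile normalization (log2 -0.15) and after scaling to the same median (-0.54), and without the 5 TA arrays of low beta-actin ratio Myh4 (-0.25) and Myh7 (-0.52) were not called. With only those 5 arrays as TA, the brightest probe set of Myh3 (0.64) and Myh2 (-0.54) were not called. Myh4 was not called with number as a replicate block (limma adjusted p = 0.055) or with the batch term for the 5 arrays (0.14). Myh2 was not called with each array as its own sample (limma adjusted p = 0.052), with number added as a random block (0.085) or with the batch term (0.068). Leaving out a single numbered sample ended the call of this Myh3 probe set without EOM replicate 4 (1.33), TA_6h replicate 1 (1.11) or TA_6h replicate 2 (limma adjusted p = 0.065). It ended that of Myh2 without EOM replicate 3 (-0.60), TA_6h replicate 1 (-0.54) or TA_6h replicate 3 (-0.58). It ended that of Myh4 without any of the 4 EOM replicates (-0.67 to -0.63), TA_6h replicate 3 (-0.53) or TA_6h replicate 4 (-0.50).

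**Figure D1:**
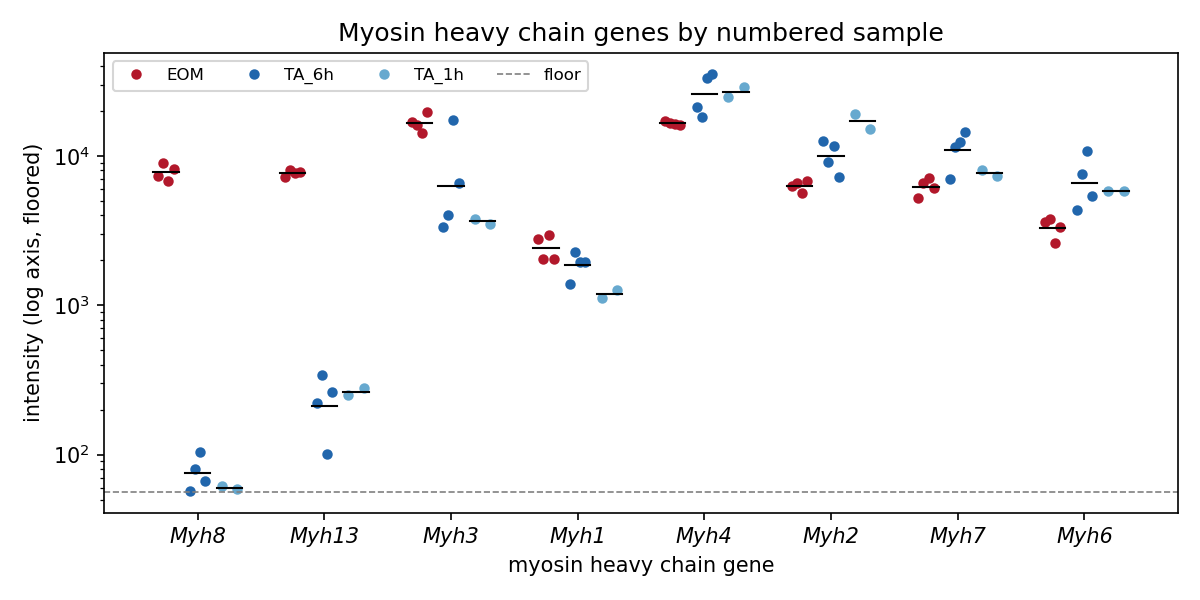
Floored intensity (log axis) of the 8 measured myosin heavy chain genes, each through its brightest probe set, in the 4 EOM, 4 TA_6h and 2 TA_1h numbered samples; points are samples, black lines geometric means and the dashed line the floor of 56.5. The 4 EOM samples of Myh8 and Myh13 lie above all TA samples, whereas the other isoforms differ from TA_6h by 2.67-fold or less.

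Beyond the myosins, the genes with the largest higher values in EOM were Ces1d (a carboxylesterase, 25.8-fold), Ccl11 (the chemokine eotaxin, at least 22.3-fold), Lum (the matrix proteoglycan lumican, 21.4-fold), Mx2 (16.8-fold), Apod (apolipoprotein D, 15.5-fold), Cidea (a lipid droplet protein, 14.9-fold), Mgst1 and Gstm5 (glutathione transferases, 13.8- and 13.7-fold), Hsd11b1 (which activates glucocorticoids, 13.8-fold) and F10 (coagulation factor X, at least 13.7-fold). Their limma adjusted p-values ran up to 0.000395, which was that of Mgst1, whose EOM samples were the most uneven at 2660 ± 2637 (SD, n = 4). The largest lower values were those of Nat2, Mpst, Dcaf6, Pdyn, Pfkfb1, Ube2g2, Dpm2, Lipe, Inf2, Spop, Smarcd2 and Slc6a9. In 10 of these 12 genes all EOM arrays lay at the floor and the mean deposited EOM intensity was below 0, as for Nat2 (an N-acetyltransferase, -2150 ± 456 in EOM and 6535 ± 1380 in TA_6h, at least 112-fold lower) and Lipe (hormone-sensitive lipase, at least 28.5-fold lower). Dcaf6 alone of the 12 was above the floor on all 16 arrays (log2 -5.83 ± 0.61). Among probe sets above the floor on all 16 arrays, a set chosen after the data were seen, the lower genes after Dcaf6 were Arhgef7 (-3.37 ± 0.32), Map1a (-3.24 ± 0.31), Ghrh (-3.20 ± 0.37), Fbp2 (a muscle fructose bisphosphatase, -3.13 ± 0.20), Mapt (-3.03 ± 0.60), Abcb6 (-2.89 ± 0.31), Dhrs7c (-2.81 ± 0.22), Csrp3 (a Z-disc protein, -2.79 ± 0.38), Mybpc2 (fast myosin-binding protein C, -2.77 ± 0.23), Mogs (-2.65 ± 0.56) and Aldh1l1 (-2.64 ± 0.22). Without EOM replicate 4 the differences of Mapt and Mogs were -2.31 and -2.06, and without EOM replicate 2 that of Pdyn was -5.99, against -5.33 with it. Of the tested probe sets of a gene, only 1 of 5 was called for Ghrh, 1 of 3 for Arhgef7, 1 of 3 for Nat2 and 2 of 4 for Pfkfb1.

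In all, 3606 of 7640 probe sets were called between EOM and TA_6h, 1671 higher and 1935 lower in EOM. The excess of lower calls depended on the processing. The calls were 1834 higher and 1765 lower after quantile normalization, 1862 and 1715 after scaling to the same median, and 1576 and 1434 with a floor at the 40th percentile. They were 1674 higher and 2792 lower with a floor at the 10th percentile and 1697 and 2406 with log2(value + 50) in place of the floor. Of the lower calls, 680 (35.1%) had every EOM array at the floor and 959 (49.6%) had an EOM intensity below 0, while 19 of the higher calls had every TA_6h array at the floor. In the 680 the floored EOM samples are equal, so their p-values take no spread from EOM and can be too small. Among the 4041 probe sets above the floor on all 16 arrays the calls were 1136 higher and 791 lower. Of 457 genes with several called probe sets, 133 (29.1%) had calls in opposite directions, and on the probe sets above the floor on all 16 arrays 34 of 189 (18.0%) did. The median difference over all tested probe sets was -0.11, and it was 0.03 after quantile normalization and -0.02 after scaling to the same median; differences are given without subtracting it. The negative intensities, present in EOM alone, point to another summary method for EOM, and these counts do not separate muscle from method. Differences of Ccl11, F10, Ocm, S100b, Sptan1, Krt5 and Cast, with at most 4 of 8 TA_6h arrays above the floor, are lower limits of size on the log2 scale. So are those of Pdyn, Pfkl, Calb2, Hlf, Ppard, Cspg4, Cma1 and Muc1, with at most 2 of 4 EOM arrays above the floor.

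Proteins of fast contraction and carbohydrate use included many lower members. In the fast-fibre list 8 of 14 measured members were lower and 0 higher, among them Mybpc2, Myl1 (fast myosin light chain, log2 -1.04 ± 0.15), Eno3 (muscle enolase, -1.02 ± 0.26) and Mylk2 (-0.86 ± 0.15); the list as a whole was not called (camera adjusted p = 0.066, and 0.63 with an estimated correlation). It was called lower in 6 of 27 alternatives, with camera adjusted p-values over all of them from 0.0195 to 0.35. These were probe sets above the floor on all 16 arrays (camera adjusted p = 0.027), a floor at the 40th percentile (0.0495), no filter (0.032) and the intensity trend (0.038). The others were the fits without TA_6h replicate 2 (0.027) and with only the 5 TA arrays of low beta-actin ratio as TA (0.0195). Of 13 members of glycogen metabolism 6 were lower and 0 higher, including Gaa (-2.15 ± 0.27), Ppp1r1a (-2.13 ± 0.31), Gsk3b (-1.94 ± 0.40) and Pgm1 (-1.60 ± 0.18) (camera adjusted p = 0.11). This list was called lower in 1 of 27 alternatives, that of probe sets above the floor on all 16 arrays (camera adjusted p = 0.027, over the alternatives 0.027 to 0.43). Of 24 members of glycolysis 12 were lower and 3 higher (camera adjusted p = 0.17): Pfkfb1 was at least 40-fold lower, Gpd1 at least 12.7-fold, Fbp2 8.77-fold and Pfkl, above the floor on 1 of the 4 EOM arrays, at least 5.43-fold. The log2 difference of Gpd1 was -2.77 without TA_6h replicate 2, -2.82 without replicate 1, -4.4998 without replicate 4 and -4.60 without replicate 3, against -3.67 with all samples. It was -6.31 without the 5 TA arrays of low beta-actin ratio and -1.03 with only these as TA. The other probe set of Pgm1 with the widest spread had a difference of 0.63 that was not called. In the slow-fibre list 3 of 10 members were higher and 4 lower, with Pln (phospholamban, 2.43 ± 0.25) and Casq2 (1.27 ± 0.41) higher and Csrp3 and Myl3 (-1.83 ± 0.24) lower. Among embryonic, neonatal and cardiac isoforms 7 of 19 were higher and 8 lower, with Myl4 (2.81 ± 0.25) and Nppb (2.44 ± 0.60) higher and Ankrd1 (-3.18 ± 0.34) lower. Of 47 members of oxidative phosphorylation and the citrate cycle 5 were higher and 10 lower, with Slc25a5 (1.78 ± 0.29), Atp5if1 (1.19 ± 0.22) and Cox6a1 (0.92 ± 0.31) higher and Ndufv3 (-0.98 ± 0.28) lower. Of 37 members of fatty acid uptake and oxidation 5 were higher and 11 lower, with Cd36 (a fatty acid transporter, 3.02 ± 0.86) higher and Ppard (-4.32 ± 0.48), Ucp3 (-1.78 ± 0.55) and Acads (-1.60 ± 0.29) lower. Without TA_6h replicate 3 Cd36 differed by 2.41, without the 5 TA arrays of low beta-actin ratio by 1.33, with these as a batch term by 1.45 and with only these as TA by 4.72.

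Membrane and synaptic genes moved in both directions. Of 17 measured neuromuscular junction genes 6 were higher and 4 lower in EOM. The acetylcholine receptor subunit Chrna1 (log2 2.04 ± 0.27) and the growth factor Ptn (2.09 ± 0.24) were higher, Ncam1 was at least 4.12-fold lower, and Utrn was at least 14.5-fold lower through its brightest probe set and called higher through another. Ncam1 differed by less through another probe set (log2 -1.15, limma adjusted p = 0.0051). Its named probe set differed by -0.83 with a floor at the 40th percentile. The receptor subunits Chrne (1.35 ± 0.22), Chrnd (1.34 ± 0.16) and Chrng (0.68 ± 0.17), named after their values were seen, were also called higher. In calcium handling 7 of 40 members were higher and 13 lower, with the calcium binder Ocm at least 7.03-fold higher and Cacnb1 (-2.77 ± 0.48) and the voltage sensor Cacna1s (-2.53 ± 0.19) lower. Calb2 was lower (-2.56 ± 0.43), with 1 of 4 EOM arrays above the floor. Another probe set of Cacna1s had a difference of 0.77 that was not called. Of 21 channels, pumps and transporters 5 were higher and 7 lower, with Slc4a3 (1.91 ± 0.16) higher, Kcnj12 (-2.46 ± 0.24) and Kcnj11 (-1.89 ± 0.25) lower and Kcna5 at least 3.42-fold lower. In the dystrophin complex list 3 of 22 members were higher and 9 lower, with Sptan1 (2.08 ± 0.27) and Vim (vimentin, 2.02 ± 0.17) higher and Tln1 (-2.80 ± 0.52) lower. Among 38 myogenic regulators and growth factors 9 were higher and 10 lower, with Igf1 (2.81 ± 0.19, with another probe set called lower) and Id2 (1.97 ± 0.25) higher, Myog (myogenin) at least 13.9-fold lower and Igf2r (-2.33 ± 0.66) lower, the last by -2.98 without EOM replicate 1 and -1.70 without EOM replicate 4.

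Matrix and nerve genes were higher as groups. In the extracellular matrix and fibroblast list 19 of 36 measured members were higher and 4 lower, led by Lum, Spp1 (osteopontin, log2 2.93 ± 0.19), Omd (2.82 ± 0.22) and Fbln5 (2.73 ± 0.19). The list median was 0.81 (camera adjusted p = 0.010, and adjusted p = 0.61 with an estimated correlation). Of 20 nerve and Schwann cell markers 12 were higher and 3 lower, with S100b (3.17 ± 0.26), the myelin genes Mbp (3.09 ± 0.17) and Pmp22 (2.96 ± 0.29) and the synaptic Snap25 (2.56 ± 0.31, with another probe set called lower) higher (camera adjusted p = 0.010, and adjusted p = 0.17 with an estimated correlation). In the antioxidant and detoxifying list 11 of 31 members were higher and 1 lower, with Gsta1 (2.29 ± 0.24) and Gsta4 (1.70 ± 0.24) beside Mgst1 and Gstm5 (camera adjusted p = 0.029, and adjusted p = 0.17 with an estimated correlation). Of 36 cytosolic ribosomal proteins 11 were higher and 1 lower, including Rpl41 (1.55 ± 0.27), Rps10 (1.06 ± 0.16), Rpl5 (0.98 ± 0.26) and Rpl35a (0.92 ± 0.20) (camera adjusted p = 0.031, and adjusted p = 0.62 with an estimated correlation). Among probe sets above the floor on all 16 arrays the nerve list (camera adjusted p = 0.15), the antioxidant list (0.098) and the ribosomal list (0.14) were not called, and after quantile normalization the antioxidant list (0.11) was not called. The former setting called 3 lists, matrix higher (0.027) and the fast-fibre and glycogen lists lower, in place of 4 higher. With only the 5 TA arrays of low beta-actin ratio as TA the nerve (0.054), antioxidant (0.055) and ribosomal (0.29) lists were not called, and with a floor at the 40th percentile the antioxidant (0.063) and ribosomal (0.063) lists were not called. The ribosomal list was also not called without EOM replicate 1 (0.067), TA_6h replicate 1 (0.068) or TA_6h replicate 2 (0.090). Over the alternatives camera adjusted p-values ran from 0.00044 to 0.036 for the matrix list, 0.0076 to 0.15 for nerve, 0.0076 to 0.11 for antioxidant and 0.00074 to 0.29 for ribosomal.

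Other cell markers were mixed. Of 30 immune markers 13 were higher and 3 lower, with Cd53 (log2 2.84 ± 0.18), Aif1 (2.58 ± 0.18, with another probe set called lower) and Lyz2 (lysozyme, 2.55 ± 0.21) higher and the mast cell protease Cma1 (-2.73 ± 0.58) lower (camera adjusted p = 0.10). The list was called in 1 of 27 alternatives, with probe sets above the floor on at least 10 arrays (camera adjusted p = 0.045, over the alternatives 0.045 to 0.18), and without EOM replicate 1 Cma1 differed by -3.34. Of 18 adipocyte markers 8 were higher and 4 lower, with Cidea, Scd2 (3.75 ± 0.20, with another probe set called lower) and Scd (2.78 ± 0.47) higher and Lipe lower. Endothelial markers were 3 higher and 2 lower of 11, with Vcam1 (1.71 ± 0.49) and Icam1 (1.06 ± 0.34) higher, Icam2 at least 2.84-fold lower and Thbd (-1.07 ± 0.22) lower through 1 probe set and called higher through another. Smooth muscle and pericyte markers were 4 higher and 3 lower of 10, with Cald1 (3.11 ± 0.36), Myh11 (5.66-fold) and Tagln (1.61 ± 0.31) higher and Cspg4 (-2.07 ± 0.26) lower; another probe set of Tagln was called lower. Of 19 orbital gland and ocular tissue markers 3 were higher (Rom1 2.4999 ± 0.30, Krt5 1.83 ± 0.28 and Pip 1.48 ± 0.30) and 4 lower, Muc1 (-2.40 ± 0.40) among them. Of 6 red blood cell markers 2 were lower, Car2 (-1.35 ± 0.24) and Hbb-b1 (beta-globin, -0.75 ± 0.21). Of 43 immediate early and stress genes 13 were higher and 17 lower, with Hsph1 (-2.51 ± 0.23), Nr4a1 (-2.40 ± 0.42), Dnajb1 (-2.23 ± 0.28) and Cebpb (-2.04 ± 0.18) lower. Of 9 clock genes 1 was higher, Bhlhe41 (1.39 ± 0.17), and 4 were lower, including Hlf (-2.32 ± 0.39), Bhlhe40 (-0.80 ± 0.30) and Tef (-0.60 ± 0.16). Of 34 protein breakdown genes 10 were higher and 9 lower, with Cast (1.80 ± 0.53) and Psmb9 (1.73 ± 0.22) higher and Trim63 (a muscle ubiquitin ligase, -2.41 ± 0.63) and Ctsd (-1.72 ± 0.32) lower. Trim63 differed by -1.16 without the 5 TA arrays of low beta-actin ratio, -1.28 with these as a batch term and -3.66 with only these as TA, and by -4.59 through its other probe set.

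Of the tested probe sets of a list member, 1 of 3 was called for Pgm1, 2 of 3 for Cox6a1 and 2 of 4 for Cast. For Ndufv3, Ucp3, Cacna1s, Myh11, S100b, Pmp22, Scd, Pip, Car2, Hsph1, Hlf, Ctsd and Gsta4 1 of 2 was called. Some calls of named genes lay near the threshold and ended when a sample was left out, often with little change in the difference. Casq2 was not called without EOM replicate 1, 3 or 4 or TA_6h replicate 3 or 4 (log2 0.99 to 1.30 without these), nor Cox6a1 without any EOM replicate or TA_6h replicate 1 or 2 (0.73 to 0.94). Gpd1 was not called without any EOM replicate (-3.67) or TA_6h replicate 1 (-2.82) or 2 (-2.77), nor Ucp3 without EOM replicate 2 (-1.42) or 4 (-1.62) or TA_6h replicate 1 (-1.40) or 2 (-1.69). Icam1 was not called without EOM replicate 2, 3 or 4 or TA_6h replicate 2, 3 or 4 (0.94 to 1.09), nor Cast without TA_6h replicate 3 or 4 (1.47), and another probe set of Cast had a difference of -0.81. Bhlhe40 was not called without EOM replicate 1 or 3, either TA_1h replicate, or TA_6h replicate 1, 2 or 3 (-0.89 to -0.62). Scaling to the same median ended the calls of Ndufv3 (-0.87), Hbb-b1 (-0.64) and Bhlhe40 (-0.69), and quantile normalization that of Chrng (0.45). A floor at the 40th percentile ended those of Gpd1 (-2.53), Icam2 (-0.29) and Rpl5 (0.39). Without the 5 TA arrays of low beta-actin ratio Casq2 (0.47), Igf2r (-2.57), Icam1 (0.90), Cast (0.79), Rpl5 (0.56) and Myh6 (-0.79) were not called, and with only these as TA Nppb (2.39), Ucp3 (-1.08), Igf2r (-2.08), Vcam1 (0.99), Cma1 (-2.88) and Bhlhe40 (-0.36) were not called. The sizes of other differences also moved by over 1.5-fold with these arrays. Without the 5 arrays and with only these as TA, the differences were -5.12 and -6.54 for Dcaf6, -4.32 and -5.74 for Ube2g2, 1.73 and 3.28 for Myh11, 2.15 and 3.40 for Scd and -1.60 and -3.20 for Nr4a1. They were 2.19 and 0.64 for Myh3, 0.47 and 2.08 for Casq2, -2.48 and -1.08 for Ucp3, 2.44 and 0.99 for Vcam1 and 0.79 and 2.81 for Cast. With the batch term Gsk3b differed by -1.33 and Cox6a1 by 1.504. Where a group lay at the floor the size followed the floor, as for Nat2 with -8.83 at the 10th and -5.56 at the 40th percentile. Other probe sets of Gstm5 (4.81), Kcnj11 (-3.54), Psmb9 (2.57) and Atp5if1 (1.92) gave larger differences than those named.

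Of the 8 measured myosin heavy chain genes 3 were called higher and 4 lower. The list's median (-0.14) was negative while its mean (1.32) and test direction were positive (camera adjusted p = 0.68). The embryonic list had a median of -0.30 and a mean of 0.25 and tested down (camera adjusted p = 0.97), and the myogenic (median 0.07, mean -0.06) and gland (0.17 and -0.01) lists tested up. Camera adjusted p-values of the lists not given one above ran from 0.32 to 0.97. Adjusted over the list alone, counts against TA_6h differed from those over all probe sets in 11 lists: embryonic isoforms 7 higher and 9 lower, glycolysis 4 and 12, oxidative phosphorylation 3 and 6, fatty acid oxidation 4 and 11, dystrophin complex 4 and 9, myogenic regulators 9 and 11, immune markers 13 and 4, adipocyte markers 8 and 5, immediate early genes 14 and 17, antioxidant enzymes 10 and 1, ribosomal proteins 10 and 0. No list called in a comparison with EOM was called with an estimated correlation. In the nerve (0.0015) and antioxidant (0.00046) lists the estimate lay under the preset 0.01. A higher correlation between members is therefore not what ended the calls of these lists.

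**Figure D2:**
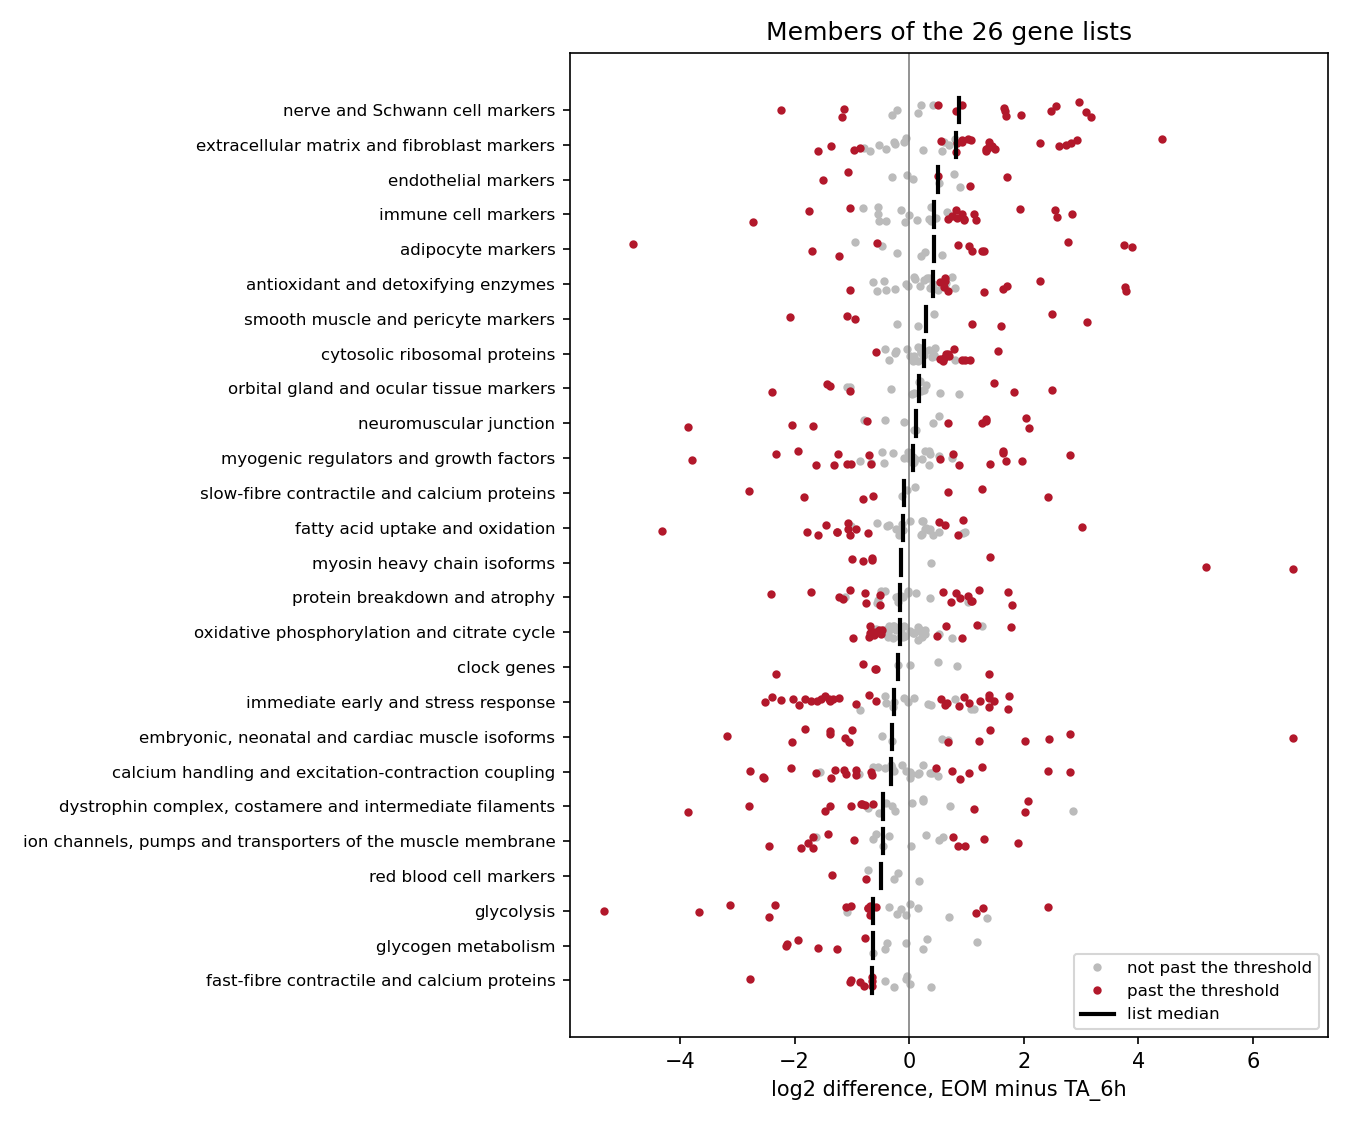
Log2 difference between EOM and TA_6h for each measured member of the 26 gene lists (horizontal axis), with probe sets past the limma threshold in red, others in grey and list medians as black bars. Nerve (median 0.87) and matrix (0.81) lists lie to the right, and fast-fibre (-0.65), glycogen (-0.64) and glycolysis (-0.63) lists to the left.

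The comparison with TA collected at 1 hour asks the same of the smaller TA group. Apart from the myosin heavy chains, named whatever their result, the genes named here were chosen as called in both comparisons. Both comparisons share the EOM samples. Myh8 (log2 7.02) and Myh13 (4.87) were higher in EOM by similar sizes, as were Ces1d (5.11), Ccl11 (4.77), Lum (4.65) and Mx2 (4.41), and Fbp2 (-3.35) and Mybpc2 (-2.81) were lower. The sizes of Myh8, Ccl11 and Mx2 are lower limits set by the floor, with 2, 1 and 3 of 4 TA_1h arrays above it. Myh3 was higher (2.19). Myh2 was lower (-1.43), Myh1 was called higher here (1.02), and Myh4 (-0.69), Myh7 (-0.30) and Myh6 (-0.81) were not called through their brightest probe sets. The other probe set of Myh7 was called lower (-1.22, limma adjusted p = 0.020). The matrix list held 20 higher and 2 lower of 36 members (median 1.10, camera adjusted p = 0.00012, and adjusted p = 0.47 with an estimated correlation), and the nerve list 12 and 2 of 20 (camera adjusted p = 0.0055, and adjusted p = 0.14 with an estimated correlation). Antioxidant enzymes (10 and 0 of 31, camera adjusted p = 0.015, and adjusted p = 0.14 with an estimated correlation) and immune markers (12 and 2 of 30, camera adjusted p = 0.016, and adjusted p = 0.47 with an estimated correlation) were higher as lists. The fast-fibre list was lower (1 higher and 8 lower of 14, camera adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation), and lost its call in 5 of 27 alternatives. These were quantile normalization (0.28), the widest-ranging probe set per gene (0.059), the fit of single arrays with number as a random block (0.064), the fit without the 5 TA arrays of low beta-actin ratio (0.051) and that with the batch term (0.061). Over the alternatives its camera adjusted p-values ran from 0.00017 to 0.28. Adjusted over the list alone the counts were 21 and 3 for matrix and 1 and 9 for fast fibres, and the same as above for nerve, antioxidant and immune lists. The other 21 lists were not called (lowest camera adjusted p = 0.086, for glycogen and ribosomal lists). Among probe sets above the floor on all 16 arrays the nerve (0.13) and antioxidant (0.059) lists were not called. The antioxidant list was also not called after quantile normalization (0.076), with the widest-ranging probe set per gene (0.059) and with only the 5 TA arrays as TA (0.085), where TA_1h is a single sample. Its camera adjusted p-values ran from 0.0057 to 0.085 over the alternatives, and those of the nerve list from 0.0028 to 0.13. On the probe sets above the floor on all 16 arrays the glycogen (camera adjusted p = 0.017), oxidative phosphorylation (0.017) and calcium handling (0.019) lists were called lower. This made 6 lists, 2 higher and 4 lower, in place of 4 higher and 1 lower. Over the 27 alternatives the ribosomal list was called higher in 8 (camera adjusted p = 0.0086 to 0.68). Among them were quantile normalization (0.0086), a floor at the 10th percentile (0.030) and the fit without TA_1h replicate 2 (0.034). The glycogen list was called lower in 4 (0.017 to 0.55), again with TA_1h replicate 2 left out (0.034) among them. Oxidative phosphorylation was called in 2 (0.010 to 0.91), calcium handling in 1 (0.019 to 0.82) and the neuromuscular junction list, higher, in 1 (0.027 to 0.80). The call of the junction list and the lowest value for oxidative phosphorylation came with only the 5 arrays as TA. In all, 2843 probe sets were called, 1354 higher and 1489 lower in EOM, and 923 higher and 589 lower among those above the floor on all 16 arrays. They were 1473 and 1369 after quantile normalization, 1508 and 1296 after scaling to the same median, and 1310 and 1162 with a floor at the 40th percentile. With a floor at the 10th percentile they were 1379 and 2253, and with log2(value + 50) 1428 and 2025. With TA_1h replicate 1 left out the count was 1861, 965 higher and 896 lower, and without TA_1h replicate 2 it was 1926, 880 higher and 1046 lower. The remaining TA_1h sample is then assumed to vary like the other groups. Any difference in the EOM summary method is confounded here as well.

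Calls against both TA groups in the same direction numbered 2589, 1243 higher and 1346 lower, Myh8, Myh13, Lum and Fbp2 among them. Higher calls outnumbered lower calls after quantile normalization (1340 higher and 1234 lower), after scaling to the same median (1407 and 1174) and with a floor at the 40th percentile (1222 and 1009). They also did so on probe sets above the floor on all 16 arrays (845 and 524), and without TA_1h replicate 1 (922 and 838), where TA_1h is a single sample. A floor at the 10th percentile gave 1244 higher and 2115 lower, and log2(value + 50) gave 1303 and 1909. Independent lists of the same sizes would share 296 higher and 377 lower. Both contrasts use the same EOM samples. In 20 simulations with unchanged groups the shared samples gave a mean overlap of 0.05. Where no group differs, hardly any probe set can be called in either contrast. This value therefore does not show how far shared samples raise the overlap of real calls. With EOM 1 and 2 set against TA_6h and EOM 3 and 4 against TA_1h the overlap was 1739 (861 higher and 878 lower). Across probe sets, which are not independent replicates, the 2 sets of differences had a covariance of 1.496, against 0.0684 in the simulations.

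The third comparison asks what changed in TA between collection at 1 and at 6 hours. No probe set was called by limma (smallest adjusted p = 0.065, for Cpt1a, which was called with an adjusted p = 0.041 without TA_6h replicate 4), with 424 probe sets at an unadjusted p under 0.05 where 382 were expected. Cpt1a, an enzyme of fatty acid uptake into mitochondria, was at 366 ± 92.7 (SD, n = 4) at 6 hours and 93.6 ± 5.28 (SD, n = 2) at 1 hour. The matrix list (median log2 0.27, camera adjusted p = 0.0040) and the embryonic and cardiac list (0.21, camera adjusted p = 0.0040) were higher at 6 hours, as were immediate early and stress genes (0.13, camera adjusted p = 0.039), and oxidative phosphorylation was lower (-0.18, camera adjusted p = 0.0049). Each of the 4 had an adjusted p = 0.57 with an estimated correlation, and 0 members were called over all probe sets. Adjusted over the list alone, 2 embryonic and cardiac members (Ankrd1 and Dlk1), 1 fatty acid gene (Cpt1a) and, lower, 1 calcium gene (Calm2) were called, and these genes are named after their values were seen. Ankrd1, a stress-responsive muscle protein, was at 4646 ± 5151 (SD, n = 4) at 6 hours and 540 ± 295 (SD, n = 2) at 1 hour. All 4 list calls were lost with TA_1h replicate 2 left out (camera adjusted p = 0.15 to 0.54). The matrix call was also lost without TA_6h replicate 1 (0.16), the embryonic call without TA_6h replicate 3 (0.053) and without the 5 arrays (0.70, median -0.04), oxidative phosphorylation without TA_6h replicate 2 (0.12) or after quantile normalization (0.20) and the stress call without TA_1h replicate 1 (0.089) or TA_6h replicate 1 (0.16). The embryonic call was also lost with the widest-ranging probe set per gene (0.062), and the matrix call with only the 5 arrays as TA (0.31). The stress list was called in 17 of 27 alternatives, matrix in 24, oxidative phosphorylation in 24 and the embryonic list in 23. Lists not called on all TA samples were called in some alternatives. Myogenic regulators were called in 11 (lowest camera adjusted p = 0.0021), fast fibres in 6 (0.0035), immune markers in 6 (0.0092), fatty acid oxidation in 5 (0.0092), ribosomal proteins in 1 (0.015) and smooth muscle in 1 (0.046). Without TA_1h replicate 1 the myogenic (0.022), fast-fibre (0.037), immune (0.0145) and fatty acid (0.014) lists were called. Without TA_6h replicate 4 the myogenic (0.0087), fast-fibre (0.033) and fatty acid (0.021) lists were called, and without TA_6h replicate 3 the myogenic (0.032) and fast-fibre (0.0035) lists. The myogenic list was also called without EOM replicate 1 (0.0295), and smooth muscle without TA_6h replicate 1 (0.046). Without the 5 TA arrays of low beta-actin ratio, a choice made after the data were seen, 45 probe sets were called, 33 higher and 12 lower at 6 hours. That fit compared TA_6h replicates 1 and 2 with TA_1h replicates 1 and 2, the last on a single array. With the 5 arrays as a batch term 17 were called. With only these 5 arrays as TA, where TA_1h is a single sample, 681 were called.

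RNA quality was compared through control probe sets. The beta-actin 3′ over 5′ ratio had geometric means of 1.199 in EOM, 1.32 in TA_6h and 1.57 in TA_1h, and the differences in log2 were -0.14 between EOM and TA_6h (exact permutation p = 0.51), -0.39 between EOM and TA_1h (exact permutation p = 0.27) and -0.25 between TA_6h and TA_1h (exact permutation p = 0.60). The Gapdh ratio was 0.945 in EOM, 0.658 in TA_6h and 0.749 in TA_1h, higher in EOM than in TA_6h by 0.52 on the log2 scale, with all 4 EOM samples above all 4 TA_6h samples (exact permutation p = 0.029, the smallest that 4 against 4 samples can give, and 0.20 after adjustment over 9 tests). The beta-actin middle over 3′ ratio, a measure added after the data were seen, was 0.929 in EOM, 0.552 in TA_6h (exact permutation p = 0.43 against EOM) and 0.550 in TA_1h (exact permutation p = 0.067 against EOM). With 2 TA_1h samples the smallest exact permutation p is 0.067, so these comparisons could not reach 0.05.

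**Figure D3:**
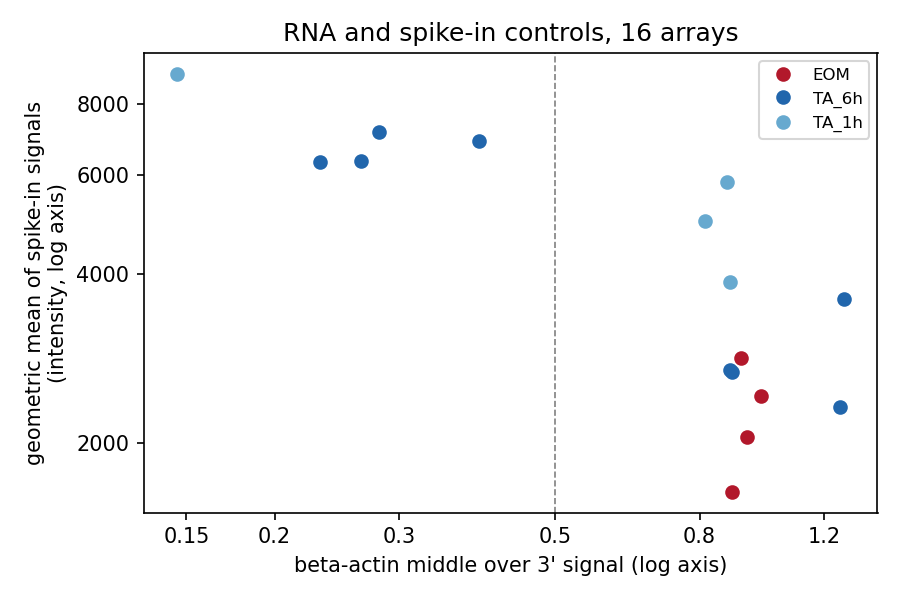
Geometric mean of the bacterial spike-in control intensities (log axis) against the beta-actin middle over 3′ ratio (log axis) on all 16 arrays, coloured by group; the dashed line marks 0.5. The 5 TA arrays left of the line have spike-in means of 6328 to 9066, above the 2320 to 5821 of the other 7 TA arrays.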

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

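Values of the named genes and of the RNA quality ratios were screened for a numbered sample far from the others of its group; the screen covered 268 groups of 4 samples and marked 12, where chance alone would mark about 13.4. The value given is the gap to the nearest sample divided by the group's whole range. In 6 of the groups the value is 1 because the other samples lie at the floor of 56.5: EOM replicate 2 stood alone for Pdyn (346), Hlf (197) and Pfkl (66.0), EOM replicate 4 for Calb2 (230), and TA_6h replicate 4 for F10 (71.0) and Ocm (62.4). Ctsd was high in EOM replicate 2 (0.926; 4430 against a geometric mean of 1769 in the others) and Cspg4 in EOM replicate 4 (0.905; 119 against 57.8). In TA_6h, Aldh1l1 was high in replicate 4 (0.905; 1834 against 1147), Psmb9 (0.991; 323 against 197) and Myl1 (0.856; 31546 against 23757) in replicate 3, and Aif1 was low in replicate 2 (0.865; 100.3 against 129).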

How the results depend on the processing

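Settings added after the data were seen are those on all-16-array probe sets, the 5 TA arrays, the batch term, the 4-fold minimum and the beta-actin middle ratio. Of 3616 values of 131 named genes under the alternatives 3507 kept direction and call, 103 lost the call (13 through the 2-fold minimum) and 6 reversed; 102 of the 130 genes called kept call and direction throughout. Restricting to probe sets above the floor on all 16 arrays gave 1927 calls against TA_6h, 1512 against TA_1h and 1369 shared, because fewer probe sets were tested, and 1 between the TA groups. Requiring 4-fold gave 796, 848 and 655. Between the TA groups 8 were called without the filter, 1 with each array as its own sample, 45 without the 5 arrays, 681 with only these, and 17 with the batch term; the cause was not tested. List calls between the TA groups fell to 2 after quantile normalization and to 2 with the widest-ranging probe set per gene, and rose to 8 with the batch term; list calls against TA_6h fell to 2 with only the 5 arrays; the cause was not tested. Leaving out each numbered sample gave 3156 to 3514 calls against TA_6h, 1861 to 3045 against TA_1h (lowest without TA_1h replicate 1), 1760 to 2652 shared and 0 to 1 between the TA groups, and 3 to 4, 5 to 7 and 0 to 7 lists. The widest-ranging probe set reversed Myh6 (1.98), Pgm1 (0.63), Cacna1s (0.77), Thbd (1.18), Tagln (-2.50) and Cast (-0.81). With only the 5 arrays the stress list between the TA groups turned down by camera with a median of 0.0735 (adjusted p = 0.94). The Gapdh difference between EOM and TA_6h (0.52) had an exact permutation p of 0.13 with each array as its own sample, and the beta-actin middle difference between EOM and TA_1h (0.76) then had 0.029. The matrix list kept its call against both TA groups in all 27 alternatives. The ribosomal list kept its call against TA_6h in 21 and the antioxidant list in 23. All 27 used the preset correlation, and with an estimated correlation none of these calls was kept. The label number as a replicate block gave 3507, 2540, 0 and 2356 calls; same-numbered samples correlated at 0.10, 0.02, 0.03 and 0.07 between EOM and TA_6h, 0.39 and -0.42 between TA_6h and TA_1h, and 0.04 and -0.04 between EOM and TA_1h. As not every pair correlated, the numbers were not taken to pair samples. Probe sets near the floor of 56.5, and EOM values below 0, limit what can be measured.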

Other observations

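Genes that differ between the TA hours without the 5 arrays of low beta-actin ratio were chosen after their values were seen. That fit holds only replicates 1 and 2 of each hour, with TA_1h replicate 2 on a single array. Collagen genes Col1a1 (log2 1.92) and Col1a2 (2.01), the matrix proteoglycan Fmod (4.03), the heat shock gene Hspa1a (2.01), the myogenic regulator Myog (1.21) and Cpt1a (1.57) were higher at 6 hours, and Ntrk2 (-1.90) and Grip2 (-2.09) were lower. On all TA arrays the same probe sets differed by 1.35, 1.34, 3.02, 1.72, 1.00, 2.04, -1.12 and -1.40, and none was called by limma. Not every gene called without the 5 arrays kept its direction. Tpm1 was called higher there (1.75) and differed by -1.06 on all TA arrays, where it was not called. Without TA_6h replicate 3 Fmod (3.67) was called (limma adjusted p = 0.014), and without TA_6h replicate 4 Cpt1a (1.88) was called (limma adjusted p = 0.041). Grip2 differed by -2.03 without TA_1h replicate 2 and by -0.77 without TA_1h replicate 1, and was called in neither fit.

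The split of the 8 numbered samples into EOM and TA_6h was set against all 35 splits of these samples. Only the real split, 1 of 35, gave as many calls (3606, against a highest other of 0) and as many lists (4, against a highest other of 3). Every other split mixes EOM with TA_6h samples. Their difference then widens the spread, so call counts near 0 were set in advance. For lists the margin was small, with 4 against 3. A share of 1 of 35 is the smallest this test can give, so it does not show how far chance is excluded. The split follows the EOM and TA summary methods as well as the muscle. The tests on the matrix, nerve and immune lists and on the 5 TA arrays were chosen after these patterns were seen, as were the comparison values of other probe sets of the same gene.

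Lower calls whose EOM arrays all lie at the floor may come from the summary method of the EOM arrays. If these genes were lower in extraocular muscle, their other probe sets above the floor on all 16 arrays would also be lower, in over 75% of genes by the bound set before the test. They were lower in 79 of 146 genes, 54.1% (exact 95% interval 45.7 to 62.4%), against 44.5% of all such probe sets. For calls above the floor on all 16 arrays, a second probe set kept the direction in 61.7% of 222 lower and 67.05% of 264 higher genes, so the bound was too strict to decide. A probe set above the floor on all 16 arrays is also less often found where EOM expression is low. Summary method and lower expression cannot be told apart for these calls.

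The matrix and nerve lists were called higher against TA_6h, and immune markers, called against TA_1h alone, were weighed with them. The median difference of the 86 members from TA_6h was 0.68, at percentile 100 of 10000 random sets matched on TA intensity, but the lists were pooled after they were seen to be high, so this restates the pattern and leaves the summary method open. The gland and ocular list had a median of 0.17, at percentile 80.0 of its matched sets, so tissue taken along with the muscle could neither be shown nor excluded. A lower share of muscle fibres would raise other cell types alike, and the medians of 6 lists of other cell types did not differ by more than reassigned members gave (permutation p = 0.81), which leaves it open. A difference between the muscles in these cell types was not tested and may hold as well.

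The 5 TA arrays that stand apart could reflect collection hour, but 1 of the 5 is TA_1h and 4 are TA_6h, and arrays of both hours are among the other 7, which argues against the hour as the cause. Less labelled sample RNA or brighter scaling of these arrays is a candidate for their spike-in signals only. Their lowest mean log2 spike-in signal lies 0.12 above the highest of the other 7. Scaling multiplies a whole array, so it cannot account for the low beta-actin ratio that defines the 5 arrays. What lowered that ratio was not tested. Apart from collection hour, no biological explanation was tested for these arrays.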
